A study of Homo sapiens with 19 samples.

How the data were processed

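RNA of 19 libraries of mesHMLE cells was sequenced by the authors with single-end reads of 75 cycles. Per the labels, microRNAs were transfected at 10 nM and siRNAs at 20 nM in total, the DZIP1 plasmid was given 6 h before the small RNA, media were changed after 6 h, and RNA was taken at 72 h. The labels describe RNaseH-treated total RNA with strand-specific libraries and elsewhere polyadenylated RNA, and which holds was not settled here. The deposited values are counts, whole numbers of reads per gene with 1 column per library, without normalization. The submitters' processing notes name FastQC 0.11.9, STAR without a version and the hg38 build. They do not state the counting tool, the strand setting or the gene annotation. All 19 columns matched a sample label (0 columns were left over), and totals ran from 5099708 to 64880593, a ratio of 12.7. Of 28216 genes in the table, 25505 symbols matched 1 gene of GENCODE 29, which gave positions, 3' UTRs, transcript length and GC content (94.1% of the tested genes had the last pair). Replicates of a group (14 pairs) had correlations of log2 CPM of at least 0.965, and their spread exceeded counting error by 8.84 to 70.4 times (chi-square per degree of freedom), so depth alone did not set the errors printed. Errors of means are SD between libraries and errors of log2 fold changes are SE computed from the fold change and the F statistic.

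Groups were taken from the labels, and the choices of test, threshold, lists, named genes and alternatives were fixed before the data were examined, apart from those said to be chosen afterwards. All libraries went into 1 fit in R 4.3.3 with edgeR 4.0.16, using filterByExpr (15936 genes kept), TMM factors, 1 mean per group for 8 groups, no block, and edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The fit had 11 residual degrees of freedom, a prior of 6.31 and a common biological coefficient of variation of 0.161. The comparisons were miR-200c against Scr, DZIP1 siRNA and IFT siRNA each against NC siRNA, DZIP1 OE with Scr against Scr, DZIP1 OE with miR-200c against DZIP1 OE with Scr, the interaction of plasmid and miR-200c, DZIP1 OE with miR-200c against miR-200c, the knockdowns against each other, Scr against NC siRNA, and DZIP1 OE with Scr against DZIP1 OE alone.

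The 16 gene lists were written from general knowledge: miR-200 targets, epithelial genes, mesenchymal genes, intraflagellar transport, basal body with transition zone and BBSome, Hedgehog signalling, TGF-beta targets, actin cytoskeleton and adhesion, cell cycle, interferon response, NF-kB and inflammatory genes, p53 targets, unfolded protein response, cholesterol synthesis, Notch signalling, and markers of other cell types (immune, endothelial, adipocyte). They were tested in 6 comparisons (96 tests) with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided), with the targets DZIP1, IFT20 and IFT88 left out and Benjamini-Hochberg adjustment over the 96. With an estimated correlation 4 of the 23 calls hold, epithelial genes with miR-200c without and with the plasmid, mesenchymal genes with IFT siRNA, and interferon genes with the plasmid. Fry, which asks whether a list's genes move on balance in a direction and does not compare them with other genes, called 6. Some lists share genes, such as CFL2, FHOD1 and MSN of the miR-200 targets and the actin genes, and TAGLN, ACTA2 and TPM1 of the TGF-beta targets and the actin genes. Genes shared by pairs of comparisons were tested with a one-sided Fisher exact test over the 15936 genes, which takes the comparisons as independent. The knockdowns share their control libraries, so for that pair chance overlap is higher than the test assumes. Seed sites were tested with a two-sided permutation test within 10 bins of 3' UTR length (100000 resamples), adjusted over 5 comparisons. A scan of all 7-mers (16150 motifs, 11179 genes, 1000 permutations) was added for the closing section. It centred values by length and GC content of the 3' UTR, and its means for the seed are also given beside the seed test.

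The labels do not state what the replicate numbers mark. By a rule fixed beforehand, applied to each comparison after both fits had been seen, libraries with the same first number were taken as paired where a comparison has 3 or more such pairs and in each the departures from the group means correlate over 0.1. This held for miR-200c against Scr (4 pairs, lowest r 0.227), miR-200c after the plasmid (3, 0.202), Scr against NC siRNA (3, 0.159) and DZIP1 OE with Scr against DZIP1 OE (3, 0.203). It failed for the plasmid with Scr (4 pairs, −0.173) and with miR-200c (3, −0.0619), and the knockdown comparisons have 2 pairs each. So the pairing comes from the values and not from the labels. The main fit stayed without a block, and the blocked value stands beside a result whose call it changes, apart from some that are not reported here.

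Genes were named by rule. DZIP1, IFT20 and IFT88 were named in every comparison. In each of the 5 main comparisons the rule added the 5 largest rises and the 5 largest falls among genes past the threshold with an average log2 CPM of at least 2 and every library of 1 group above every library of the other (3 each way in the other comparisons). From each list it added the 2 members with the smallest adjusted p past the threshold. Genes named outside the rule are said to be so.

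The test was tried on simulated data with the real depths and spread, 100 genes each at log2 fold changes of 1 and 2 and 15736 unchanged. It called 85 and 99 of the changed genes for miR-200c against Scr with 5 false calls, 79 and 100 for DZIP1 siRNA with 5, 72 and 99 for IFT siRNA with 17, 90 and 99 for the plasmid with 8, and 67 and 99 for miR-200c after the plasmid with 6. The changed genes had an average log2 CPM of at least 2, so these rates do not cover lower ones. The simulation held no library classes or replicate numbers, so its false calls do not cover errors from them. In 96 simulated list tests a shift was put into 1 list in the miR-200c group. It was called for miR-200c against Scr, and 0 of the tests without a shift were called. The shift also entered the interaction, whose result is not given here. The seed test gave a permutation p of 0.769 without a shift and recovered −0.0969 of a shift of −0.1.

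Alternatives were RLE and upper quartile factors, no low-count filter and a stricter one (1 CPM in 3 libraries and an average log2 CPM of 1), a fit of the compared groups alone, replicate numbers as a block, libraries of a group with the same first number summed, limma-voom, DESeq2 1.42.0, a threshold of 2-fold added to the adjusted p, camera with an estimated correlation, fry, other seed sites, no length bins, and each library left out in turn. Chosen after the data were seen were the library class as a term, fits within a class, offsets for GC content and length, these offsets with a replicate block, leaving out the 3 shallowest libraries together, and Scr libraries as controls for the knockdowns. Where a library left out leaves 1 in its group, that library is assumed to vary like the other groups. Sequence work and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9. The siRNA sequences were not used here, and no protein or cilium measurements were analysed here.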

Results

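Transcripts were counted in 19 RNA sequencing libraries of mesHMLE cells, a mesenchymal derivative of the immortalised human mammary epithelial line HMLE that was obtained by at least 14 days in TGF-β1, a cytokine that induces epithelial to mesenchymal transition. The libraries formed 8 groups. Cells received a negative control siRNA (NC siRNA, 2 libraries), an siRNA against DZIP1 (2), siRNAs against IFT20 and IFT88 given together (IFT siRNA, 2), a scrambled microRNA (Scr, 3), the microRNA miR-200c (3), a plasmid for DZIP1 fused to a fluorescent protein (DZIP1 OE, 2), that plasmid followed by Scr (3), or that plasmid followed by miR-200c (2). RNA was taken 72 h after transfection. The series title names primary cilia, miR-200 and DZIP1 as its subject.

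The deposited counts per library, in units of 1e6, were 45.4 and 30.9 for NC siRNA (replicates 1.1 and 2.1), 35.3 and 52.1 for DZIP1 siRNA (1.2 and 2.1), and 28.1 and 64.9 for IFT siRNA (1.1 and 2.1). Scr had 5.10, 35.5 and 35.2 (replicates 1.1, 1.2 and 2.2), and miR-200c had 14.4, 6.35 and 39.97 (1.1, 2.1 and 2.2). DZIP1 OE had 42.9 and 27.7 (1.1 and 2.2), DZIP1 OE with Scr had 26.6, 8.91 and 29.5 (1.1, 2.1 and 2.2), and DZIP1 OE with miR-200c had 37.5 and 42.9 (1.2 and 2.2). Between 15938 and 19703 genes were detected per library, and 15936 were tested. The labels do not say what the replicate numbers stand for, so a p-value for a gene below measures spread between these libraries and not between independent cell cultures. The permutation and Fisher p-values take genes as units and do not measure spread between libraries. The strand setting of the counting is not stated, so levels of genes that overlap on opposite strands are uncertain.

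The libraries also differed in a way the groups do not fully explain: the relation of gene level to GC content split them into 3 classes, a split seen in the data. Class A held the 8 libraries whose replicate number ends in 2 (correlation with GC content across genes −0.07 to 0.09). Class B held 6 libraries ending in 1 without a microRNA oligonucleotide (0.40 to 0.62), and class C the 5 ending in 1 with one (−0.62 to −0.32). miR-200c and Scr each had libraries in classes A and C, IFT siRNA and NC siRNA lay in class B alone, and values within a class are given beside pooled ones where a class holds both sides of a comparison. Within a class, at least 1 group of every comparison other than IFT siRNA against NC siRNA has a single library.

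The 3 intended targets changed in the groups made to change them. DZIP1 encodes a zinc finger protein of the basal body that takes part in cilium formation and Hedgehog signalling (ENSG00000134874.17, GRCh38 chromosome 13, 95578202 to 95644703, minus strand). It measured 82.1 ± 0.791 counts per 1e6 counts (CPM, mean ± SD, n = 2) with NC siRNA and 22.1 ± 1.35 (n = 2) with DZIP1 siRNA. IFT20 and IFT88 encode subunits of the intraflagellar transport machinery that builds cilia (ENSG00000109083.13, chromosome 17, 28328325 to 28335489, minus strand, and ENSG00000032742.17, chromosome 13, 20567069 to 20691437, plus strand). IFT20 went from 29.6 ± 1.38 to 7.9 ± 0.457 CPM and IFT88 from 19.1 ± 1.31 to 8.05 ± 1.4 CPM with IFT siRNA (n = 2 each). With the plasmid, counts assigned to DZIP1 measured 225 ± 76.8 CPM (n = 2) alone, 238 ± 40.6 (n = 3) with Scr and 221 ± 40.6 (n = 2) with miR-200c, against 82.6 ± 6.12 (n = 3) with Scr alone, and these counts do not separate plasmid from endogenous transcripts.

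Transfection of miR-200c, a microRNA that represses the transcription factors ZEB1 and ZEB2, posed the question of which transcripts change when it is returned to mesenchymal cells. Of 15936 genes, 723 changed against Scr (3 libraries each), 459 higher and 264 lower, and 249 and 90 of these by at least 2-fold. CDH1, which encodes E-cadherin of epithelial junctions (chromosome 16, 68737225 to 68835548), rose from 4.31 ± 2.51 to 31.8 ± 5.21 CPM, a log2 fold change of 2.95 ± 0.385 (SE; adjusted p = 1.84e-04). The microtubule-binding MAP7 rose by 3.13 ± 0.192 (adjusted p = 9.86e-08), and ANXA3, MISP and FGFBP1 rose by 3.33, 3.31 and 2.90 (adjusted p of 5.79e-05, 6.37e-04 and 2.71e-05). ZEB1 (chromosome 10, 31318495 to 31529814) fell from 14.9 ± 2.26 to 7.66 ± 0.795 CPM (log2 fold change −0.92 ± 0.169, adjusted p = 0.00333) and ZEB2 (chromosome 2, 144364364 to 144524583) from 57.6 ± 18.8 to 25.5 ± 4.33 (−1.195 ± 0.209, adjusted p = 0.00228). The largest falls were in LOC728392 (−1.95), SIRPA (−1.79), the adhesion gene CADM3 (−1.70), the collagen gene COL5A3 (−1.58) and GPR162 (−1.58), with adjusted p from 7.24e-05 to 0.00582.

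Epithelial genes rose as a group with miR-200c. Of 42 measured, 27 were higher and none lower (35 and 0 adjusted over the list alone), 15 were not called over all genes, and 41 had log2 fold changes above 0 with a median of 1.24. The cell polarity gene CRB3 (3.34, adjusted p = 2.54e-05), the lipid synthesis gene CDS1 (2.76, adjusted p = 8e-06) and CDH1 were among them, as were EPCAM (2.72), the splicing factor ESRP1 (4.29) and the transcription factor GRHL2 (4.05), which were picked after their values were seen. Among 37 genes listed as miR-200 targets, 11 fell and none rose (12 lower and 2 higher adjusted over the list alone), including the RNA-binding QKI (−1.13, adjusted p = 1.15e-04), the secretory coat gene SEC23A (−1.06, adjusted p = 4.45e-05) and the actin-severing CFL2 (−0.94, adjusted p = 4.21e-04). Their median was −0.175. Of 37 mesenchymal genes, 3 fell, ZEB1, ZEB2 and COL6A1 (−0.74, adjusted p = 0.0143), and none rose (9 lower and 1 higher adjusted over the list alone). With the first replicate number as a block, PRRX1 (−1.34, adjusted p = 0.0314) and TWIST2 (−0.57, adjusted p = 0.036) fell as well. The intermediate filament gene VIM (0.01, adjusted p = 0.973) and the matrix gene FN1 (−0.18, adjusted p = 0.787), picked afterwards, were not called. Against all other genes, limma's camera gave an adjusted p of 1.14e-30 for epithelial genes (adjusted p = 0.00466 with an estimated correlation), 2.13e-04 for miR-200 targets (adjusted p = 0.364 with an estimated correlation) and 0.118 for mesenchymal genes. The family held 96 tests, of 16 lists in 6 comparisons, and the lists of targets and mesenchymal genes share ZEB1, ZEB2 and FN1.

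**Figure D1:**
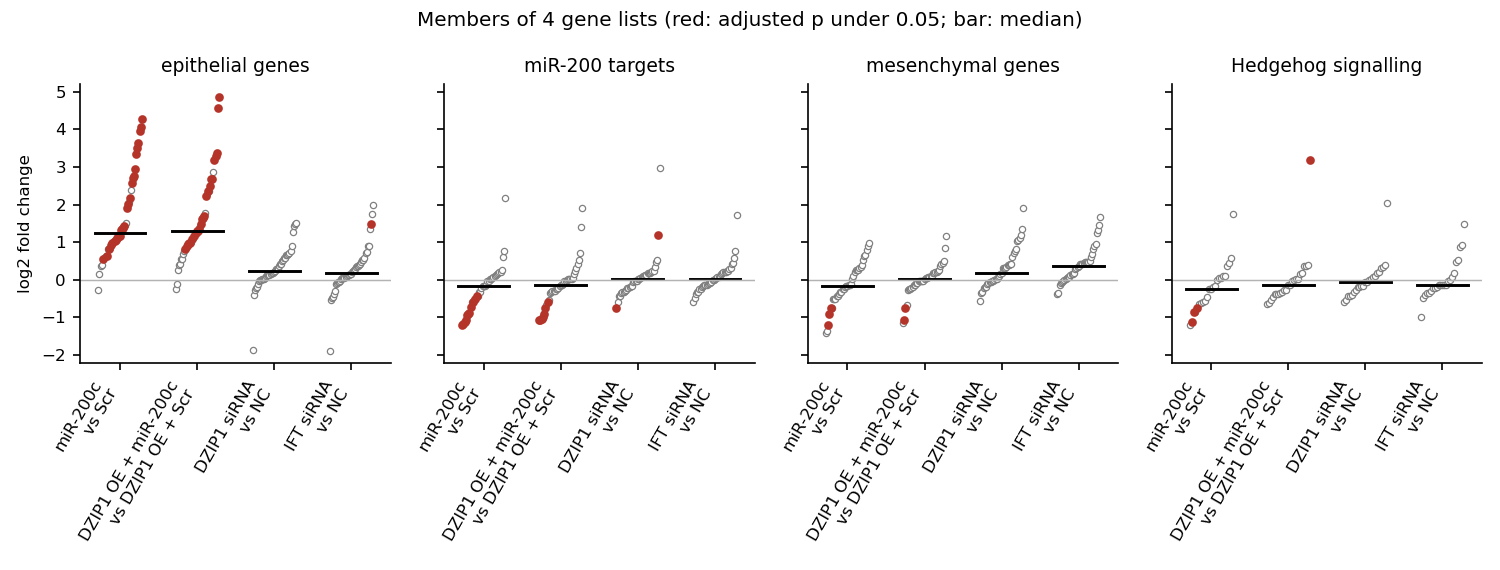
Log2 fold changes of list members in 4 comparisons, 1 panel each for epithelial genes, miR-200 targets, mesenchymal genes and Hedgehog signalling; points are genes, red ones have an adjusted p under 0.05 and bars are medians. Epithelial genes had medians of 1.24 with miR-200c and 1.31 with miR-200c after the plasmid, against 0.229 with DZIP1 siRNA and 0.187 with IFT siRNA.

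Transcripts of the cilium and of Hedgehog signalling, which depends on cilia, were examined next with miR-200c. DZIP1 measured 56.5 ± 3.55 CPM against 82.6 ± 6.12 with Scr (n = 3 each), a log2 fold change of −0.56 ± 0.164 that missed the threshold (adjusted p = 0.0614), and it was −0.69 within class A and −0.40 within class C. It passed in some other settings, among them DESeq2 (adjusted p = 0.0315) and a fit with the library class as a term (0.0388), the latter chosen after the data were seen. With the first replicate number as a block, which pairs these libraries, it was −0.62 (adjusted p = 0.014). IFT20 (0.08, adjusted p = 0.81) and IFT88 (0.02, adjusted p = 0.97) were not called. Of 29 intraflagellar transport genes only IFT172 passed, lower (−0.49 ± 0.128, adjusted p = 0.0347), and of 57 genes of the basal body, transition zone and BBSome none did. Their medians were −0.0209 and −0.0167, with adjusted p of 0.448 and 0.861 by camera. Of 23 Hedgehog genes 3 fell and none rose (6 and 0 adjusted over the list alone): the signal transducer SMO, from 31.9 ± 3.85 to 17.8 ± 1.83 CPM (−0.85 ± 0.138, adjusted p = 0.00132), and the transcription factors GLI2 (−0.75, adjusted p = 0.0233) and GLI1 (−1.13, adjusted p = 0.0233; named because it was the third member called). The list as a whole had a median of −0.234 and an adjusted p of 0.0534 (adjusted p = 0.902 with an estimated correlation), and passed with the block (adjusted p = 0.0381). PTCH1, a pathway target picked afterwards, stood at −0.85 (adjusted p = 0.0676). With the block PTCH1 (−0.91, adjusted p = 0.0202) and GLI3 (−0.635, adjusted p = 0.0261) also fell, and SHH rose (2.02, adjusted p = 0.042).

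Further groups of genes were compared between miR-200c and Scr. All 25 genes of the unfolded protein response had log2 fold changes above 0 (median 0.242), and ATF3 (1.34), TRIB3 (1.76) and the chaperone gene HSPA5 (0.74, outside the naming rule) were called, with adjusted p of 0.0144, 0.016 and 0.0486. The list passed with camera (adjusted p = 0.00122, and adjusted p = 0.902 with an estimated correlation). NF-kB and inflammatory genes had a median of 0.444 with 0 of 24 called (3 higher adjusted over the list alone, and SAA1 called with the block, adjusted p = 0.0413) and an adjusted p of 0.00234 for the list (adjusted p = 0.902 with an estimated correlation). Cell cycle genes had a median of −0.119 with 0 of 38 called and an adjusted p of 0.0239 (adjusted p = 0.902 with an estimated correlation, and 0.143 with the block, where it was not called). Camera did not call the 7 remaining lists, whose adjusted p ran from 0.0879 for cholesterol synthesis to 0.928 for the interferon response. Among their members, INSIG1 (0.66, adjusted p = 0.0145) and CYP51A1 (0.43, adjusted p = 0.038) of cholesterol synthesis, the p53 target TP53I3 (0.66, adjusted p = 0.0247), the Notch gene DTX4 (1.06, adjusted p = 8.39e-04), and the actin genes TPM4 (0.91, adjusted p = 0.00136), LPP (0.83) and PALLD (0.55) rose. SMAD6 of the TGF-beta targets (−0.92, adjusted p = 0.0485), IFITM1 of the interferon response (−1.27, adjusted p = 0.0489) and the actin genes CFL2, FHOD1 (−0.88) and RDX (−0.59) fell, LPP, PALLD, FHOD1 and RDX being outside the naming rule. TGF-beta targets had 4 higher and 1 lower adjusted over the list alone, actin genes 5 and 4, Notch genes 1 and 1, p53 targets 2 and 0, and cholesterol genes 2 and 0. Markers of immune, endothelial and fat cells, of which 8 of 23 listed passed the count filter, had 0 called, a median of −0.323 and an adjusted p of 0.393. For the interferon list the median (0.0372) and the mean (−0.0388) differed in sign.

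The call count with miR-200c depended on the libraries. It was 412 without Scr 1.2, 350 without miR-200c 2.1 and 402 without miR-200c 2.2, 247 without the 3 shallowest libraries, and 159 in a fit of these 2 groups alone. Within class A (3 libraries) and within class C (3) edgeR called 0 genes, with 1206 and 972 at an unadjusted p under 0.05, and the fold changes of all genes in the 2 classes correlated at 0.384. The epithelial median was 1.35 within class A and 1.10 within class C, that of miR-200 targets −0.206 and −0.0494, and that of Hedgehog genes −0.206 and −0.0352. Without miR-200c 2.1 the calls of CYP51A1, INSIG1, GLI2, IFITM1, IFT172, TP53I3, SMAD6, ATF3 and TRIB3 ended, with adjusted p from 0.0581 to 0.174. All but GLI2 also lost their calls without Scr 1.2 (0.0714 to 0.212). Some did so without Scr 1.1 (CYP51A1, IFITM1 and TRIB3, 0.0518 to 0.094), Scr 2.2 (GLI2 at a fold change of −0.50, TP53I3 and SMAD6, 0.0804 to 0.17), miR-200c 1.1 (CYP51A1, GLI2 and SMAD6, 0.0662 to 0.127) or miR-200c 2.2 (IFITM1, IFT172, TP53I3, SMAD6, ATF3 and TRIB3, 0.0741 to 0.183). The cell cycle list was not called without Scr 1.1 (0.194), Scr 1.2 (0.0972), miR-200c 2.1 (0.0725) or miR-200c 2.2 (0.192). The NF-kB list was not called without Scr 1.1 (0.104), Scr 1.2 (0.051) or miR-200c 2.1 (0.0526).

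Genes with a site for the miR-200c seed stood lower on average than others after miR-200c. The 2288 tested genes with the 7-mer CAGTATT in an annotated 3' UTR and 11017 without it, matched by 3' UTR length, differed in mean log2 fold change by −0.0733 ± 0.0144 (SE; two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 2.5e-05 over 5 comparisons). It fell to −0.0425 without miR-200c 2.2. The 624 genes with the 8-mer CAGTATTA differed by −0.134. The 1664 genes with only the 7-mer lay near those without a site when not matched by length. Their median was −0.0282 against −0.0202, and their 25th percentile −0.1919 against −0.1950. They were not tested apart from the 8-mer genes. With the plasmid present the 7-mer difference was −0.151 ± 0.0132 (permutation p = 1e-05, adjusted p = 2.5e-05). It was −3.21e-04 with DZIP1 siRNA (permutation p = 0.973) and −0.0183 with IFT siRNA (permutation p = 0.0485, adjusted p = 0.0606). The plasmid with Scr gave 0.032 ± 0.00851, in the opposite direction (permutation p = 4e-05, adjusted p = 6.67e-05), which became −0.00228 without Scr 1.2. These bins do not match GC content. The scan of 7-mers centred values by length and GC content of the 3' UTR, and 2048 genes there carried CAGTATT. Their mean was 0.00392 with the plasmid and Scr, −0.0707 with miR-200c and −0.0649 with miR-200c after the plasmid. So neither the opposite direction nor the larger difference with the plasmid was seen with GC content centred. Of 419 shuffled 7-mers, 0 gave a difference as low as the seed in miR-200c against Scr with all libraries, the lowest being −0.0451, which is lower than the seed without miR-200c 2.2. Their median was 0.0314, so shuffled 7-mers were not centred on 0. The DZIP1 3' UTR (ENST00000347108.7, 4031 nt) held 4 copies of the 7-mer, at chromosome 13 positions 95582194 to 95582200, 95582066 to 95582072, 95582042 to 95582048 and 95580422 to 95580428, and 0 of the 8-mer. The 3' UTRs of ZEB1 and ZEB2 held 5 copies each, 3 and 4 of them 8-mers, QKI and CFL2 held 3 each, and those of IFT20 and IFT88 held 0.

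Knockdown of DZIP1 posed the question of which transcripts follow the loss of this basal body protein. Against NC siRNA (2 libraries each) 32 genes changed, 15 higher and 17 lower, of which 10 and 10 by at least 2-fold. Apart from DZIP1 itself (−1.90 ± 0.203, adjusted p = 5.87e-04), the largest falls were in the proteasome assembly chaperone PSMD10, from 45.1 ± 2.22 to 15.1 ± 2.6 CPM (−1.58 ± 0.204, adjusted p = 0.00263), and the ATP synthase subunit ATP5F1D (−1.36, adjusted p = 0.0262). The protein disulfide isomerase PDIA6 fell from 561 ± 27.1 to 255 ± 14.1 CPM (−1.14 ± 0.151, adjusted p = 0.00297), and AMMECR1 fell as well (−1.12, adjusted p = 0.0327). The largest rises were in the collagen gene COL8A1, from 32 ± 8.63 to 131 ± 0.336 CPM (2.03 ± 0.299, adjusted p = 0.00617), WFDC21P (1.89, adjusted p = 0.0474), the growth factor binding genes IGFBP4 (1.64, adjusted p = 0.00716) and IGFBP3 (1.55, adjusted p = 0.00487), and the complement gene C3 (1.26, adjusted p = 0.00712). IFT20 (0.06, adjusted p = 0.969) and IFT88 (0.39, adjusted p = 0.603) were not called.

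No cilium gene other than DZIP1 was called by edgeR's quasi-likelihood test with DZIP1 siRNA: 0 of 29 intraflagellar transport genes, 0 of 57 basal body genes and 0 of 23 Hedgehog genes, before and after adjusting over each list alone. Their medians were 0.0543, 0.0369 and −0.0505, and camera gave adjusted p of 0.478, 0.448 and 0.457. Camera called epithelial genes (median 0.229, 34 of 42 above 0, 0 called singly, adjusted p = 0.00361, and adjusted p = 0.902 with an estimated correlation) upward. It also called mesenchymal genes (median 0.178, 24 of 37 above 0, 0 called singly and 2 adjusted over the list alone, adjusted p = 0.00515, and adjusted p = 0.364 with an estimated correlation) upward. Actin genes (median 0.0443, 29 of 46 above 0, adjusted p = 0.0407, and adjusted p = 0.902 with an estimated correlation) were called upward too. Of the actin genes 1 was called, TPM4, which encodes a tropomyosin (1.22, adjusted p = 0.00667; 3 higher adjusted over the list alone). Of the miR-200 targets CRKL fell (−0.75, adjusted p = 0.0212) and LEPR rose (1.20, adjusted p = 0.0474), the list's median was 0.0103 and its adjusted p 0.768. PDIA6 was the 1 called member of the unfolded protein response (list median 0.195, adjusted p = 0.212). The other 8 lists were not called (adjusted p from 0.0889 for the interferon response to 0.928 for markers of other cell types) and held 0 called genes. Adjusted over the list alone, 1 TGF-beta target was higher (COL4A1, 0.77) and 2 Notch genes were lower (DLL1, −1.62, and NRARP, −1.22). The median and the mean differed in sign for NF-kB genes (−0.0401 and 0.131), p53 targets (0.0156 and −0.0115) and markers of other cell types (−0.182 and 0.0611).

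With 2 libraries a side, leaving out any library left an arm of 1 and ended calls. The count of 32 was 13 without NC siRNA 1.1, 3 without NC siRNA 2.1, 13 without DZIP1 siRNA 1.2 and 1 (DZIP1) without DZIP1 siRNA 2.1. In that last case PSMD10, PDIA6, COL8A1 and IGFBP3 had an adjusted p of 0.101, C3, TPM4 and LEPR 0.114, ATP5F1D 0.114, IGFBP4 0.196, CRKL 0.304, AMMECR1 0.318 and WFDC21P 0.438. The log2 fold changes there were −1.43 for PSMD10, −1.10 for PDIA6, 2.01 for COL8A1, 1.48 for IGFBP3 and 1.18 for TPM4, near those of all libraries, and 1.11 for IGFBP4 (1.64 with all). Without NC siRNA 2.1 the adjusted p was 0.0809 for PDIA6, 0.227 for IGFBP3, and 0.251 for COL8A1 and TPM4. ATP5F1D, AMMECR1, WFDC21P, IGFBP4, C3, CRKL and LEPR were not called without either NC siRNA library (0.0641 to 0.275 without 1.1 and 0.251 to 0.725 without 2.1), and ATP5F1D, AMMECR1, WFDC21P and LEPR not without DZIP1 siRNA 1.2 (0.0722 to 0.387). Within class B (3 libraries) 90 genes were called and DZIP1 stood at −1.96. The epithelial list was not called without NC siRNA 2.1 (adjusted p = 0.125), the mesenchymal list without NC siRNA 1.1 (0.163) or DZIP1 siRNA 2.1 (0.0625), and the actin list without NC siRNA 1.1 (0.189) or DZIP1 siRNA 2.1 (0.341).

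Knockdown of IFT20 and IFT88 together, which encode parts of the transport machinery of cilia, served as a comparison for DZIP1. Against NC siRNA 35 genes changed (2 libraries each), 19 higher and 16 lower, of which 12 and 7 by at least 2-fold. IFT20 fell by 1.91 ± 0.157 and IFT88 by 1.26 ± 0.183 on the log2 scale (adjusted p of 1.08e-05 and 0.0042), and DZIP1 was at −0.15 (adjusted p = 0.932). EDN1, which encodes the vasoconstrictor endothelin, rose from 2.94 ± 0.468 to 10.5 ± 1.58 CPM (1.83 ± 0.353, adjusted p = 0.0382). COL8A1 rose from 32 ± 8.63 to 105 ± 4.77 (1.71 ± 0.296, adjusted p = 0.0169) and IGFBP3 from 11.5 ± 1.88 to 34.9 ± 8.91 (1.59 ± 0.218, adjusted p = 0.0042). LINC01806 (1.64, adjusted p = 0.00467) and the epithelial gene LAD1 (1.47, adjusted p = 0.0465) also rose. Falls were led by SIRPA (−1.54, adjusted p = 0.0209), the translocon gene SSR1, from 290 ± 2.69 to 125 ± 18 CPM (−1.21 ± 0.17, adjusted p = 0.0042), and C5orf15 (−1.16, adjusted p = 0.0245).

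Mesenchymal genes stood higher as a group with IFT siRNA: 30 of 37 were above 0 with a median of 0.372, 0 were called singly, 5 were higher adjusted over the list alone, and the list had an adjusted p of 2.66e-06 by camera (adjusted p = 0.0329 with an estimated correlation). TGF-beta targets (median 0.371, 0 of 28 called, 4 higher and 1 lower adjusted over the list alone, adjusted p = 0.0117), epithelial genes (median 0.187, LAD1 called, adjusted p = 0.0123) and actin genes (median 0.097, adjusted p = 0.0239) were also called upward, each with adjusted p = 0.902 with an estimated correlation. Of the actin genes TPM4 rose, from 443 ± 130 to 1070 ± 72 CPM (1.27 ± 0.184, adjusted p = 0.0042), and the profilin gene PFN2 fell (−0.74, adjusted p = 0.0169), with 4 higher and 1 lower adjusted over the list alone. Apart from the knocked-down pair, edgeR called 0 of 29 transport genes (median 0.00859, adjusted p = 0.768), 0 of 57 basal body genes (median 0.0113, adjusted p = 0.588) and 0 of 23 Hedgehog genes, with 0, 0 and 2 adjusted over the list alone. The Hedgehog list had a median of −0.141 and a mean of 0.0124 with an adjusted p of 0.719. The other 9 lists were not called, from 0.0592 for the cell cycle and 0.633 for miR-200 targets to 0.936 for the unfolded protein response, and held 0 called genes (MCM4 of the cell cycle and NRARP of Notch lower adjusted over the list alone). The median and the mean differed in sign for interferon genes (−0.0309 and 0.0372) and p53 targets (−0.0102 and 0.121).

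The IFT siRNA count of 35 was 11 without NC siRNA 1.1, 1 (IFT20) without NC siRNA 2.1, 20 without IFT siRNA 1.1 and 2 (IFT20 and IGFBP3) without IFT siRNA 2.1. Without NC siRNA 2.1 adjusted p was 0.104 for IFT88 and SSR1, 0.155 for IGFBP3 and TPM4, 0.209 for C5orf15, 0.211 for LINC01806, 0.219 for PFN2, 0.341 for SIRPA, 0.609 for COL8A1, 0.792 for EDN1 and 0.863 for LAD1. IFT88 was also not called without NC siRNA 1.1 (0.0515) or IFT siRNA 2.1 (0.167), and the other named genes apart from IGFBP3 had an adjusted p of 0.0724 to 0.543 without IFT siRNA 2.1. SIRPA, COL8A1, EDN1 and LAD1 were not called without any 1 of the 4 libraries, C5orf15 and PFN2 not without NC siRNA 1.1 (0.153 and 0.115), and LINC01806 not without IFT siRNA 1.1 (0.063). The epithelial list was not called without NC siRNA 2.1 (0.218) or IFT siRNA 1.1 (0.134), the TGF-beta list without NC siRNA 1.1 (0.321), and the actin list without NC siRNA 1.1 (0.178) or IFT siRNA 1.1 (0.055). A fit of the class B libraries alone, which hold this whole comparison, called 159 genes, with IFT20 at −1.89 and IFT88 called as well.

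Several genes rose with miR-200c and with both knockdowns. DZIP1 siRNA and IFT siRNA shared 8 risers where 0.0179 would be expected of independent comparisons (one-sided Fisher exact test, p = 4.7e-21). These comparisons share the NC siRNA libraries, so chance overlap is higher and this p overstates the evidence. The shared risers were AOX1, C3, COL8A1, IGFBP3, NTN4, SVIL, TPM4 and ZNF681, and all 8 also rose with miR-200c. COL8A1 rose by 2.03, 1.71 and 1.88 in the 3 comparisons, IGFBP3 by 1.55, 1.59 and 1.51, and TPM4 by 1.22, 1.27 and 0.91. AOX1 (0.87, 0.86 and 0.61), NTN4 (0.97, 0.99 and 0.63), SVIL (0.67, 0.65 and 0.90) and ZNF681 (1.09, 1.29 and 0.96) are named because they belong to this set. miR-200c and DZIP1 siRNA shared 13 risers (0.432 expected, Fisher exact p = 7.92e-19) and 4 fallers, CRKL, CXCL16, LGALS3BP and LOC107985939 (0.282 expected, Fisher exact p = 1.48e-04). miR-200c and IFT siRNA shared 15 risers (0.547 expected, Fisher exact p = 2.17e-20) and 3 fallers, CXCL16, SIRPA and SYT11 (0.265 expected, Fisher exact p = 0.00215), and 0 genes called in either pair moved in opposite directions. The knockdowns shared 1 faller, CXCL16 (0.0171 expected, Fisher exact p = 0.0169, with the same limit from the shared control). These fallers were named after their values were seen.

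Both knockdowns used the same NC siRNA libraries, so some likeness arises from the shared control. Fold changes correlated across genes at 0.649 ± 0.25 (jackknife SE, and genes are not independent replicates). In 20 simulated draws that shared only the control they correlated at 0.528 ± 0.014 (SD between draws). No gene was changed in these draws, so their 0 shared risers do not bear on the 8 observed. The draws also lacked the library classes and replicate numbers, so the correlations do not settle whether likeness exceeds that from the control. Across genes, miR-200c correlated with DZIP1 siRNA at 0.399 ± 0.18 and with IFT siRNA at 0.415 ± 0.098, where no control was shared. The former was 0.25 without Scr 2.2, and without a low-count filter they were 0.113 and 0.129. Against the Scr libraries, a setting chosen after the data were seen, 7 of the 8 risers kept an adjusted p of 0.0214 or lower in both knockdowns, and ZNF681 did not (0.302 and 0.0551). IFT siRNA and Scr share no library class, so class differences can enter these values. The 8 risers in common and the 1 faller (9 genes in all) became 3 without NC siRNA 1.1, 0 without NC siRNA 2.1 or DZIP1 siRNA 2.1, 5 without DZIP1 siRNA 1.2 or IFT siRNA 1.1, and 1 without IFT siRNA 2.1. The 17 genes shared by miR-200c and DZIP1 siRNA became 6 without NC siRNA 1.1, 7 without DZIP1 siRNA 1.2, 9 without miR-200c 2.1, and 0 without NC siRNA 2.1 or DZIP1 siRNA 2.1. The 18 shared with IFT siRNA became 5 without NC siRNA 1.1 or IFT siRNA 1.1, 0 without NC siRNA 2.1 and 1 without IFT siRNA 2.1.

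**Figure D2:**
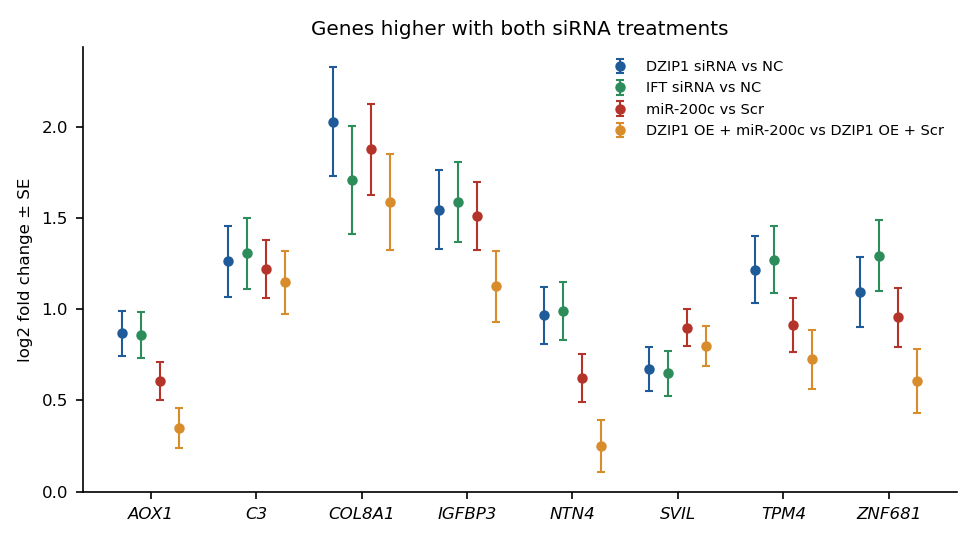
Log2 fold changes of the 8 genes higher with both knockdowns, in DZIP1 siRNA and IFT siRNA against NC siRNA, miR-200c against Scr, and miR-200c against Scr after the plasmid; points are estimates and error bars 1 SE. COL8A1 stood at 2.03, 1.71 and 1.88 in the 3 comparisons without plasmid.

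Cells given the DZIP1 plasmid and then Scr were compared with cells given Scr alone (3 libraries each), and interferon-stimulated genes were higher with the plasmid, for which the design has no group given a plasmid without DZIP1. Of 24 genes called, all higher and 20 by at least 2-fold, 17 belonged to the list of interferon response genes. IFI44 (chromosome 1, 78649796 to 78664078) rose from 1.29 ± 0.319 to 37.4 ± 23.2 CPM (log2 fold change 4.98 ± 0.549, adjusted p = 4.29e-04). The oligoadenylate synthetase genes OAS2 and OASL rose by 3.04 ± 0.371 and 4.67 ± 0.691 (adjusted p of 0.00123 and 0.00657), and IFIT3 and IFIT2, which encode antiviral RNA-binding proteins, by 2.94 and 2.62 (adjusted p of 0.0259 and 0.00766). DZIP1 rose by 1.52 ± 0.164 (adjusted p = 4.29e-04). IFT20 (0.13) and IFT88 (0.11) were not called, each with an adjusted p of 1.

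All 35 measured interferon genes had log2 fold changes above 0 with a median of 1.72, 29 were higher adjusted over the list alone, and camera gave an adjusted p of 3.82e-63 (adjusted p = 0.0143 with an estimated correlation). The rise was seen in each library given the plasmid: the list's median stood 1.92 and 1.91 above the Scr mean in DZIP1 OE, 2.17, 1.45 and 1.27 in DZIP1 OE with Scr, and 2.50 and 1.35 in DZIP1 OE with miR-200c, while the 12 other libraries lay between −0.176 and 0.22. The list median was 1.54 within class A and 1.73 within class C, where edgeR called 0 genes, with 128 and 532 at an unadjusted p under 0.05. NF-kB genes (median 0.359, 0 of 24 called, adjusted p = 4.42e-05, and adjusted p = 0.902 with an estimated correlation) were called upward. Around the mean of all libraries, their mean level was −1.27, −0.799 and 0.275 in Scr 1.1, 1.2 and 2.2. In DZIP1 OE with Scr 1.1, 2.1 and 2.2 it was 0.01, −0.0914 and 0.0938. These values lay above Scr 1.1 and 1.2 but below Scr 2.2. Cholesterol synthesis genes (median −0.231, 1 of 24 above 0, 0 called singly, adjusted p = 2.66e-06, and adjusted p = 0.638 with an estimated correlation) and cell cycle genes (median −0.0957, 0 of 38 called, adjusted p = 0.00128, and adjusted p = 0.902 with an estimated correlation) were called downward. Transport genes (−0.00981, adjusted p = 0.739), basal body genes (0.0208, adjusted p = 0.909) and Hedgehog genes (−0.106, adjusted p = 0.465) had 0 called, as did the other 9 lists, whose adjusted p ran from 0.104 for epithelial genes to 0.98. The median and the mean differed in sign for transport genes (mean 0.0106), and the test pointed up for mesenchymal genes and the unfolded protein response though their medians were −0.0109 and −8.99e-04.

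The 17 called interferon genes became 4 without Scr 1.1, 2 without Scr 1.2, 11 without Scr 2.2 and 7 without DZIP1 OE with Scr 1.1, with list medians of 1.79, 1.71, 1.74 and 1.35, and all called genes numbered 5, 3, 27 and 11. IFIT2, IFIT3 and OASL were not called without Scr 1.1 (adjusted p of 0.0617, 0.18 and 0.054) or Scr 1.2 (0.101, 0.26 and 0.0699), nor IFIT3 without DZIP1 OE with Scr 1.1 (0.15). The cell cycle list was not called without Scr 1.1 (0.124) or DZIP1 OE with Scr 2.2 (0.0682), the NF-kB list without Scr 1.1 (0.0949), and the cholesterol list without Scr 2.2 (0.147).

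**Figure D3:**
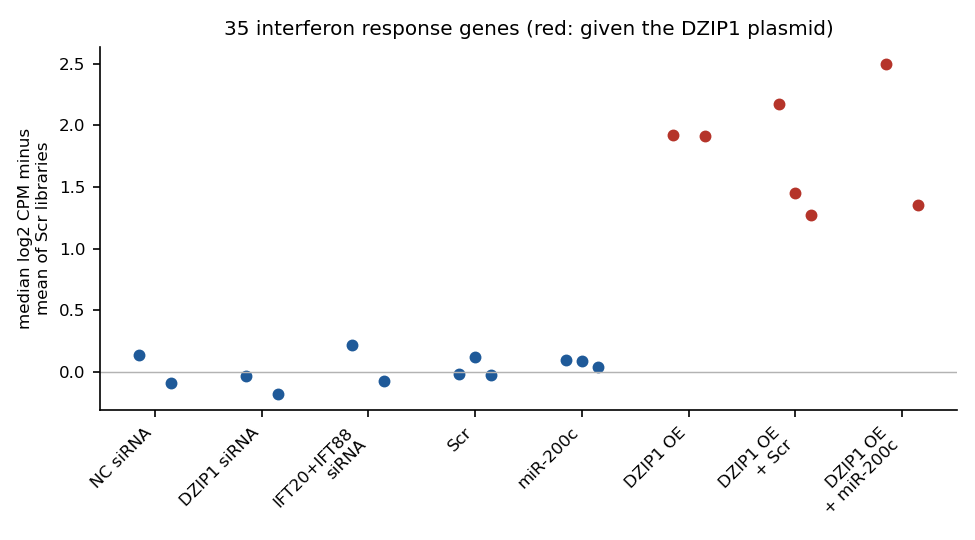
Median log2 CPM of 35 interferon response genes in each of the 19 libraries, less their mean in the Scr libraries; each point is a library and red points received the DZIP1 plasmid. The 7 libraries with plasmid lie between 1.27 and 2.50 and the 12 others between −0.176 and 0.22.

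With DZIP1 over-expressed, miR-200c was compared with Scr (2 and 3 libraries) to ask whether its effects remain when DZIP1 transcripts stay high. DZIP1 measured 221 ± 40.6 against 238 ± 40.6 CPM (−0.10 ± 0.178, adjusted p = 0.829, and from −0.30 to 0.07 with a library left out), and 331 genes changed, 247 higher and 84 lower, 169 and 28 of them by at least 2-fold. CDH1 rose from 3.22 ± 0.461 to 34.3 ± 6.08 CPM (3.38 ± 0.403, adjusted p = 1.73e-04), MISP by 3.71, MAP7 by 3.24, FGFBP1 by 2.52 and the transcription factor TFCP2L1 by 2.71 (adjusted p from 8.59e-08 to 0.00292). OSTM1 (−1.497), LOC728392 (−1.58), SYT11 (−1.21), CADM3 (−1.17) and B4GAT1 (−1.16) fell most, with adjusted p from 1e-04 to 0.00519. ZEB2 fell from 58.9 ± 4.01 to 27.8 ± 5.76 CPM (−1.08 ± 0.231, adjusted p = 0.0182) and ZEB1 from 14.3 ± 1.71 to 8.54 ± 0.145 (−0.74 ± 0.181, adjusted p = 0.0393). IFT20 (−0.07, adjusted p = 0.846) and IFT88 (−0.16, adjusted p = 0.68) were not called.

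Of 42 epithelial genes 25 rose and none fell (35 and 0 adjusted over the list alone; median 1.31, adjusted p = 4.9e-33, and adjusted p = 0.00466 with an estimated correlation), CRB3 by 3.17 and CDS1 by 2.23 among them (adjusted p of 5.03e-05 and 6.44e-05). Of 37 miR-200 targets 7 fell (7 lower and 1 higher adjusted over the list alone), with CFL2 at −1.06 and SEC23A at −0.99 (adjusted p of 6.9e-04 and 4.61e-04), and the list had an adjusted p of 0.00128 (adjusted p = 0.536 with an estimated correlation). Interferon genes (median 0.499, 34 of 35 above 0, 0 called, adjusted p = 1.37e-04) and the unfolded protein response (median 0.254, 0 of 25 called, adjusted p = 0.0407) were called upward, each with adjusted p = 0.902 with an estimated correlation. Hedgehog genes had a median of −0.152 and an adjusted p of 0.601. Their 1 called gene was the ligand SHH, which rose from 0.147 ± 0.156 to 1.68 ± 1.05 CPM (3.18 ± 0.687, adjusted p = 0.019). Transport genes (−0.112, adjusted p = 0.113) and basal body genes (−0.0436, adjusted p = 0.27) had 0 called. With the first replicate number as a block, which pairs these libraries too, TRIB3 of the unfolded protein response (1.58, adjusted p = 0.0181) rose, and the lists of TGF-beta targets and cholesterol synthesis passed upward (adjusted p of 0.0346 and 0.0233, against 0.0628 and 0.0847 without it, and each adjusted p = 0.902 with an estimated correlation and no block). Of the remaining lists (adjusted p from 0.0628 to 0.843), the actin genes DIAPH1 (0.51, adjusted p = 0.023) and TPM4 (0.72) rose and CFL2 and RDX (−0.65) fell. The inflammatory gene SAA1 (3.34, adjusted p = 0.0291) and the Notch gene DTX4 (0.95, adjusted p = 0.00519) rose. ZEB1 and ZEB2 were the 2 mesenchymal genes called, TPM4 and RDX being outside the naming rule here. For mesenchymal genes (0.0215) and markers of other cell types (0.0985) the median lay above 0 while the test pointed down. Adjusted over the list alone, transport genes had 1 higher and 1 lower, TGF-beta targets 1 higher, and actin genes 3 and 3.

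Of the genes called with miR-200c without the plasmid, 198 of the risers and 59 of the fallers were also called with it (7.11 and 1.39 expected by chance, Fisher exact p of 3.23e-275 and 9.56e-88). Fold changes correlated across all tested genes at 0.664 ± 0.19 (0.228 without a low-count filter). Over only the genes called without the plasmid, the slope through the origin was 0.793 ± 0.14. Picking genes by their call without the plasmid can by itself lower this slope, so it does not show a weaker effect with the plasmid. The test of the difference itself, the interaction, called 0 genes with edgeR (494 at an unadjusted p under 0.05, lowest adjusted p 0.899), DESeq2 or limma-voom, and DZIP1 stood at 0.45 ± 0.241 (adjusted p = 0.899), IFT20 at −0.16 (0.903) and IFT88 at −0.19 (0.904) in it. Among lists it was called for interferon genes (median 0.356, adjusted p = 1.37e-04), NF-kB genes (−0.277, adjusted p = 0.0126) and Notch genes (0.267, adjusted p = 0.0407), each with adjusted p = 0.902 with an estimated correlation. It was not called for the other 13, including epithelial genes (0.0445, adjusted p = 0.759), miR-200 targets (0.117, adjusted p = 0.448) and Hedgehog genes (0.233, adjusted p = 0.0762). In it the median differed in sign from the test for epithelial and cholesterol synthesis genes (tests downward) and from the mean for TGF-beta targets (0.0404 and −0.0635). The interferon list turned negative without DZIP1 OE with miR-200c 1.2 (adjusted p = 0.768).

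The 331 calls became 192 without DZIP1 OE with Scr 1.1, 160 without DZIP1 OE with Scr 2.1 and 72 without DZIP1 OE with miR-200c 1.2, and the 257 genes shared with the comparison without plasmid became 150 and 72 without the latter 2. Within class A (3 libraries) edgeR called 0 genes, with 630 at an unadjusted p under 0.05, the epithelial median being 1.16. Without DZIP1 OE with miR-200c 1.2 the adjusted p was 0.361 for ZEB1, 0.407 for ZEB2, 0.404 for SHH, 0.461 for SAA1, 0.464 for DIAPH1, 0.102 for B4GAT1, 0.198 for CADM3, 0.0769 for LOC728392, 0.0859 for TFCP2L1 and 0.0521 for DTX4. The call of ZEB1 also ended without each of the other libraries given here, DZIP1 OE with Scr 1.1 (0.163) and 2.1 (0.119) and DZIP1 OE with miR-200c 2.2 (0.206). Without DZIP1 OE with Scr 2.1 the values were 0.0743 for ZEB2, 0.0701 for SHH, 0.101 for SAA1 and 0.124 for DIAPH1. DIAPH1 was not called without DZIP1 OE with Scr 1.1 (0.067), SHH (0.0818) and SAA1 (0.108) not without DZIP1 OE with Scr 2.2, and DTX4 not without DZIP1 OE with miR-200c 2.2 (0.0557). The unfolded protein list was not called without DZIP1 OE with Scr 2.2 (0.282) or DZIP1 OE with miR-200c 1.2 (0.427), and the interferon list turned negative without the latter (adjusted p = 0.79).

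Against miR-200c alone, miR-200c after the plasmid raised 34 genes (2 and 3 libraries) and lowered none, 31 of them by at least 2-fold. RSAD2, OASL and IFI44, all induced by interferon, rose by 5.45 ± 1.02, 5.23 ± 0.737 and 5.10 ± 0.557 (adjusted p of 0.0262, 0.00197 and 2.59e-04), and DZIP1 by 1.98 ± 0.179 (adjusted p = 4.51e-05). The interferon genes had a median of 2.47, and 23 of the 35 were called. Of the 24 genes raised by the plasmid with Scr, 21 were also raised here (0.0512 expected, Fisher exact p = 5.46e-57). IFT20 (−0.03) and IFT88 (−0.08) were not called (adjusted p of 0.988 and 0.948). The 34 calls became 21 without miR-200c 2.1 and 9 without DZIP1 OE with miR-200c 1.2, where RSAD2 stood at 3.31 and OASL at 3.98 and neither was called (adjusted p of 0.904 and 0.0559). RSAD2 was also not called without miR-200c 1.1 (0.0605), 2.1 (0.155) or 2.2 (0.277), and within class A edgeR called 0 genes, with 201 at an unadjusted p under 0.05. The 21 shared genes became 5 without Scr 1.1, 3 without Scr 1.2, 10 without DZIP1 OE with Scr 1.1 and 8 without DZIP1 OE with miR-200c 1.2.

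Compared directly (2 libraries each), the DZIP1 and IFT knockdowns differed in 25 genes, 13 higher and 12 lower with DZIP1 siRNA. The targets stood apart as in the comparisons with NC siRNA, DZIP1 at −1.75 ± 0.203, IFT20 at 1.96 ± 0.157 and IFT88 at 1.65 ± 0.183 (adjusted p of 4.5e-04, 6.78e-06 and 3.33e-04). SSR1 was higher with DZIP1 siRNA, at 297 ± 1.81 against 125 ± 18 CPM (1.248 ± 0.17, adjusted p = 0.00215), while PSMD10 (15.1 ± 2.6 against 39.2 ± 2.77, −1.38 ± 0.203, adjusted p = 0.00409) and NT5DC2 (42.2 ± 3.2 against 102 ± 12.4, −1.27 ± 0.183, adjusted p = 0.00385) were lower. The count became 14 without DZIP1 siRNA 1.2, 6 without DZIP1 siRNA 2.1, 16 without IFT siRNA 1.1 and 7 without IFT siRNA 2.1. NT5DC2 (0.117) and PSMD10 (0.162) were not called without DZIP1 siRNA 2.1, NT5DC2 (0.128) and SSR1 (0.159) without IFT siRNA 2.1, and PSMD10 without IFT siRNA 1.1 (0.0534). Within class B 34 genes were called.

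The control treatments were also compared. Between Scr and NC siRNA (3 and 2 libraries) edgeR called 0 genes, with 2509 at an unadjusted p under 0.05 and a lowest adjusted p of 0.304, DESeq2 called 1 and limma-voom 0. Without Scr 2.2, 848 genes were called. DZIP1 (0.01), IFT20 (−0.14) and IFT88 (0.37) had adjusted p of 0.985, 0.599 and 0.308. NC siRNA lay in class B and Scr in classes A and C, so these libraries alone cannot tell control and library class apart. Only a fit with the class as a term could part them, through other groups that span classes. Between DZIP1 OE with Scr and DZIP1 OE alone (3 and 2 libraries) edgeR called 0 genes, with 1671 at an unadjusted p under 0.05, DESeq2 called 4 and limma-voom 0, and within class A (2 libraries) edgeR called 0 with 40 at an unadjusted p under 0.05. DZIP1 (0.08), IFT20 (0.09) and IFT88 (0.17) had adjusted p of 0.871, 0.8 and 0.676, and the interferon genes had a median of −0.262, with 9 of 35 above 0.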

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

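The count of interferon genes with each library left out, the fits with the library class as a term, the fits with Scr libraries as controls and the 7-mer scan were set up before their results were seen. The tests of the interferon median with each library left out, of the plasmid without DZIP1, of the amount of DZIP1 and of the class in DZIP1 siRNA alone were chosen after the result was seen.

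The effect of miR-200c with and without the DZIP1 plasmid differed, by the interaction test, for 3 lists. Interferon response genes had an adjusted p of 1.37e-04 (median 0.356, 32 of 35 above 0), NF-kB and inflammatory genes an adjusted p of 0.0126 (median −0.277, 4 of 24 above 0) and Notch genes an adjusted p of 0.0407 (median 0.267, 17 of 20 above 0), each with adjusted p = 0.902 with an estimated correlation. For the interferon list, DZIP1 OE with miR-200c 1.2 had a mean log2 level of 2.98 over the Scr mean against 1.86 in its replicate 2.2 and 2.43, 1.61 and 1.65 in DZIP1 OE with Scr, and without replicate 1.2 the list pointed down (signed log10 of p −0.212, adjusted p = 0.768). For NF-kB genes the Scr libraries themselves spread from −1.27 (1.1) and −0.799 (1.2) to 0.275 (2.2) around the mean of all libraries, and the call ended without Scr 1.1 (adjusted p = 0.297), Scr 1.2 (0.0972), DZIP1 OE with Scr 2.2 (0.0591), miR-200c 2.1 (0.122), miR-200c 2.2 (0.209) or DZIP1 OE with miR-200c 1.2 (0.0949). The Notch call ended without Scr 1.2 (0.067), Scr 2.2 (0.153), DZIP1 OE with Scr 1.1 (0.0809) or 2.2 (0.0622), miR-200c 2.1 (0.122) or 2.2 (0.119), or DZIP1 OE with miR-200c 2.2 (0.215).

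Interferon genes were higher in all 7 libraries given the DZIP1 plasmid. Against a single library as the source, the list's median fold change stayed at 1.35 or more of 1.72 whichever library was left out, with at least 34 of 35 members above 0. The number of called members fell from 17 to 4 without Scr 1.1, 2 without Scr 1.2 and 7 without DZIP1 OE with Scr 1.1, which met the rule set beforehand for a single library as the cause. That rule was set aside because 3 different libraries met it, so it does not single out any. Without the Scr pair the typical SE rose from 0.371 to 0.415 and 0.457 while the median stood at 1.79 and 1.71, but without DZIP1 OE with Scr 1.1 the SE was 0.37 and the median fell to 1.35, so that library held part of the rise. Against the library class, the median was 1.52 with the class as a term, with 4 members called. A response to any transfected plasmid could account for the pattern and cannot be told apart from one to DZIP1, since 0 groups received a plasmid without DZIP1. The amount of DZIP1 also stays open: the list's median was −0.225 with DZIP1 siRNA, where the list missed the threshold (adjusted p = 0.0889).

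Genes lower with each siRNA shared short sequences. With DZIP1 siRNA the lowest score of all 7-mers in 3' UTRs was −8.71, for GTCGTAT, beyond the most extreme of 1000 permuted scans (−4.98), and it was carried by PSMD10, PDIA6, CRKL, AMMECR1, HK1 and RFC3, 6 of the 14 called fallers with a 3' UTR other than DZIP1; it scored 0.759 with IFT siRNA. With IFT siRNA it was −9.66, for CCCTAAT (most extreme permuted −5.6), carried by 10 of 14 fallers other than the targets, including SSR1, PFN2 and C5orf15, and scoring −0.034 with DZIP1 siRNA. Both motifs were picked from the fold changes of the same comparison, so these carriers describe the pattern and do not test it. GTCGTAT occurs in 5 of 8 annotated DZIP1 transcripts and CCCTAAT in 8 of 16 IFT20 transcripts, which share sequence and are not independent. Of all transcripts near the length of 1 coding transcript per gene (7068 and 825 nt), 4.64% and 2.33% hold them. The scan included DZIP1 itself, whose 3' UTR holds GTCGTAT, so the target helped to pick that motif. A candidate explanation is seed-like pairing of the siRNAs with other transcripts, which the siRNA sequences, not used here, would settle. An opposite response to over-expression was not seen for the 16 fallers other than DZIP1, whose median with the plasmid was −0.0449 (SE 0.0544) and not above 0.2. These counts do not show which cells held the plasmid, and no group had a plasmid without DZIP1. So this does not exclude loss of DZIP1 as the cause of the falls.

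The 8 genes higher with both knockdowns (AOX1, C3, COL8A1, IGFBP3, NTN4, SVIL, TPM4 and ZNF681) had a median of 1.22 over the pair. Against chance in the shared NC siRNA libraries as the whole source, the median was 1.08 against the Scr libraries. Scr lies in classes A and C and IFT siRNA in class B, so that value can hold a class difference and does not settle the point for IFT siRNA. The library class is argued against by a median of 1.12 (SE 0.199) with the class as a term in DZIP1 siRNA alone, against 1.16 without it. IFT siRNA and NC siRNA lie in the same class, which therefore cannot part them, so the median of 1.2 over the pair with the term does not bear on it. These genes also rose with miR-200c (median 0.935). After the plasmid, with no called fall of DZIP1 counts in the culture as a whole, their median with miR-200c was 0.762 (SE 0.198, 8 of 8 above 0, 5 called). These counts do not separate plasmid from endogenous transcripts or show which cells held the plasmid. Lower DZIP1 as the route of that rise therefore cannot be excluded. A response given alike by any small RNA would also occur in the controls, each of which is itself a small RNA. The median of 0.935 over Scr with miR-200c, in libraries not used to pick the 8 genes, argues against it for that treatment. A response that differs in strength between small RNAs was not tested, so the source of the shared rise stays open.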

How the results depend on the processing

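The library class as a term, fits within a class, GC content and length offsets with or without a block, leaving out the 3 shallow libraries together and Scr libraries as controls were chosen after the data were seen. A count was taken as the same within 1.5 times of the main one, and a correlation within 1 jackknife SE. A tested value was the same if it kept its side of the threshold without a reversal. For the results that answer a comparison, settings fixed beforehand other than leaving out a library gave 195 the same, 38 stronger, 25 weaker, 2 moved and 1 reversed. Those chosen afterwards gave 67 the same, 30 stronger and 20 weaker. Leaving out 1 library gave 143 the same, 2 stronger, 39 weaker and 3 reversed. For named genes, other settings gave 1141 the same and 203 weaker and left-out libraries 298 and 137, with 36 of 86 the same without every library. For lists these were 141 and 43, and 97 the same, 36 weaker and 2 reversed. RLE and upper quartile factors kept every count within 1.5 times. Fewer libraries or a stricter threshold could account for lower counts where libraries were left out, summed or split by class, or 2-fold was asked for; for the other changes the cause was not tested.

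The calls with miR-200c (723) numbered 286 with libraries of the same first number summed, 159 in a fit of its groups alone and 339 at 2-fold or more, 1156 with the class term, 1245 with GC offsets, 1737 with these and a block, 247 without the shallow libraries, and 0 within class A or C. They were 412 without Scr 1.2, 350 without miR-200c 2.1 and 402 without miR-200c 2.2 (350 to 918 over all 6). The calls with DZIP1 siRNA (32) numbered 98 without a filter, 17 summed, 68 with its groups alone, 132 with DESeq2, 20 at 2-fold, 89 with GC offsets, 193 with offsets and block, 17 without the shallow libraries and 90 within class B. They were 13 without NC siRNA 1.1, 3 without NC siRNA 2.1, 13 without DZIP1 siRNA 1.2 and 1 without DZIP1 siRNA 2.1. The calls with IFT siRNA (35) numbered 93 without a filter, 20 summed, 137 with its groups alone, 56 with limma-voom, 111 with DESeq2, 19 at 2-fold, 76 with the class term, 107 with GC offsets, 240 with offsets and block, 19 without the shallow libraries, 159 within class B and 449 with Scr controls. They were 11 without NC siRNA 1.1, 1 without NC siRNA 2.1, 20 without IFT siRNA 1.1 and 2 without IFT siRNA 2.1.

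The calls with the plasmid and Scr (24) numbered 51 without a filter, 3 summed, 11 with its groups alone, 9 with limma-voom, 38 with DESeq2, 11 with the class term, 42 with offsets and block, 3 without the shallow libraries and 0 within class A or C. They were 5 without Scr 1.1, 3 without Scr 1.2 and 11 without DZIP1 OE with Scr 1.1 (3 to 27 over all 6). The calls with miR-200c after the plasmid (331) numbered 543 without a filter, 156 summed, 521 with DESeq2, 197 at 2-fold, 205 with the class term, 712 with offsets and block, 135 without the shallow libraries and 0 within class A. They were 192 without DZIP1 OE with Scr 1.1, 160 without DZIP1 OE with Scr 2.1 and 72 without DZIP1 OE with miR-200c 1.2 (72 to 287 over all 5). For the plasmid in the presence of miR-200c (34) they were 75 without a filter, 16 summed, 18 with its groups alone, 58 with DESeq2, 57 with offsets and block, 16 without the shallow libraries and 0 within class A, and 21 without miR-200c 2.1 and 9 without DZIP1 OE with miR-200c 1.2 (9 to 40 over all 5). Between the knockdowns (25) they were 39 with a stricter filter, 15 summed, 4 with its groups alone, 42 with limma-voom, 76 with DESeq2, 14 at 2-fold, 60 with GC offsets, 87 with offsets and block and 13 without the shallow libraries, and 14 without DZIP1 siRNA 1.2, 6 without DZIP1 siRNA 2.1, 16 without IFT siRNA 1.1 and 7 without IFT siRNA 2.1. Scr against NC siRNA, with 0 calls, gave 135 without a filter, 1 with DESeq2 and 848 without Scr 2.2, and 0 without each of the other 4 libraries. DZIP1 OE with Scr against DZIP1 OE, with 0, gave 17 without a filter and 4 with DESeq2. The interaction stayed at 0 in every setting, left-out libraries included.

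DZIP1 with miR-200c (−0.56, adjusted p = 0.0614) passed without a filter (−0.56, adjusted p = 0.0117), with DESeq2 (−0.55, 0.0315), with the class term (−0.55, 0.0388), with GC offsets (−0.62, 0.00998) and with offsets and block (−0.69, 6.16e-04), and lay between −0.613 and −0.499 with each library left out (adjusted p of 0.061 to 0.186). DZIP1 with the plasmid and Scr was not called within class A (1.505) or C (1.604), nor with miR-200c within class A (2.064). The genes shared by miR-200c and DZIP1 siRNA (17) numbered 49 without a filter, 7 summed, 11 with the groups alone, 60 with DESeq2, 26 with the class term, 42 with GC offsets, 102 with offsets and block and 7 without the shallow libraries, and 6 without NC siRNA 1.1, 0 without NC siRNA 2.1 or DZIP1 siRNA 2.1, 7 without DZIP1 siRNA 1.2 and 9 without miR-200c 2.1. Those shared with IFT siRNA (18) numbered 49 without a filter, 8 summed, 53 with DESeq2, 38 with the class term, 50 with GC offsets, 112 with offsets and block and 7 without the shallow libraries, and 5 without NC siRNA 1.1 or IFT siRNA 1.1, 0 without NC siRNA 2.1 and 1 without IFT siRNA 2.1. Those shared by the knockdowns (9) numbered 32 without a filter, 26 with the groups alone, 16 with limma-voom, 36 with DESeq2, 15 with the class term, 27 with GC offsets, 61 with offsets and block, 36 within class B and 23 with Scr controls, and 3 without NC siRNA 1.1, 0 without NC siRNA 2.1 or DZIP1 siRNA 2.1, 5 without DZIP1 siRNA 1.2 or IFT siRNA 1.1, and 1 without IFT siRNA 2.1.

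Without a filter the correlation of miR-200c with DZIP1 siRNA moved from 0.399 to 0.113 and that with miR-200c after the plasmid from 0.664 to 0.228. The 23 list calls became 4 with an estimated correlation and 6 with fry. Without DZIP1 OE with miR-200c 1.2 the interferon list turned down with miR-200c after the plasmid (signed log10 of p −0.165) and in the interaction (−0.212). The seed difference with DZIP1 siRNA (−3.21e-04) was 0.0338 without length bins, 0.0196 for the 7-mer AGTATTA, 0.0206 without NC siRNA 2.1, 0.0212 without DZIP1 siRNA 2.1 and −0.0308 without NC siRNA 1.1. With IFT siRNA (−0.0183) it was −0.0112 for the 8-mer, −0.00676 for the 7-mer AGTATTA, 0.0026 without NC siRNA 2.1 and −0.00553 without IFT siRNA 2.1. With the plasmid and Scr (0.032) it was −0.00228 without Scr 1.2. With miR-200c it lay between −0.107 and −0.0425 with each library left out, and after the plasmid between −0.189 and −0.136.

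Libraries with the same first number had departures from the group mean with a mean correlation of 0.0144 to 0.369. With the first number as a replicate block the counts were 1071 for miR-200c, 78 for DZIP1 siRNA, 55 for IFT siRNA, 35 for the plasmid with Scr, 460 for miR-200c after the plasmid, 0 for the interaction, 51 for the plasmid with miR-200c and 41 between the knockdowns, with 51, 30 and 21 genes shared. DZIP1 with miR-200c passed with it (−0.62, adjusted p = 0.014) and with the full number as a block (−0.57, 0.0428), which gave 219 calls for miR-200c after the plasmid. In the 4 comparisons that the first number pairs, the block ended the call of the cell cycle list with miR-200c (adjusted p = 0.143) and no other call of a named gene or list. It added those printed in the report, DIAPH1 with miR-200c (adjusted p = 0.0299) and genes not named there. In the comparisons of 2 pairs, and with the plasmid, where the lowest pairs stood at −0.173 and −0.0619, the libraries share only a number. Depth limits low transcripts most in Scr 1.1, miR-200c 2.1 and DZIP1 OE with Scr 2.1, at 5099708, 6347325 and 8909979 counts, and the lowest counts behind the targets were 381 for DZIP1, 145 for IFT20 and 138 for IFT88.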

Other observations

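The splits of the libraries below were set before the data were examined, and the sites in target transcripts were looked up after the scan of 7-mers had been seen.

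Within the 6 libraries of miR-200c and Scr, 2 of the 10 splits into 3 and 3 called at least as many genes as the real one, which called 723, and the highest of the others called 2049. These splits are too few for a share under 0.05. The highest split parted the libraries by the first replicate number (1.1, 1.1 and 1.2 against 2.1, 2.2 and 2.2), so it points to a structure of the samples; with the first number as a replicate block the real comparison called 1071. For DZIP1 OE with Scr against Scr, 1 of the 10 splits, the real one, called as many as 24, and the highest other called 0, again too few splits for a share under 0.05.

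The 7-mer that scored lowest with miR-200c was its own seed match, CAGTATT (score −10, rank 1 of 16150 motifs), and it ranked the same with miR-200c after the plasmid (−10.1). Of the fallers with miR-200c that have an annotated 3' UTR, 88 of 250 carried it (43 expected, Fisher exact p = 3.6e-12), against 53 of 398 risers (68.4 expected). With DZIP1 siRNA another 7-mer, ACGCGGA, also lay beyond the permuted scans (−5.09), and it occurs in 6 of 8 DZIP1 transcripts, as in 8.45% of transcripts of like length, but in the 3' UTR of 0 of 14 called fallers other than DZIP1. In DZIP1 (ENST00000347108.7) GTCGTAT lies in exon 5 of the coding sequence (chromosome 13, 95630063 to 95630069) and in exon 21 of the 3' UTR (95581830 to 95581836). In IFT20 (ENST00000395418.7) CCCTAAT lies in exon 4 of the coding sequence (chromosome 17, 28329200 to 28329206), and 0 of 7 IFT88 transcripts held it. With the plasmid and Scr 0 motifs lay beyond the permuted scans (lowest −3.19 against −4.44).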
